A study of Drosophila melanogaster with 8 samples.

How the data were processed

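Polyadenylated RNA was sequenced from exosomes released by Drosophila S2 cells and from the cells themselves. S2 is an embryonic cell line with features of macrophage-like blood cells. There were 4 exosome and 4 cell libraries, numbered 1 to 4 in both groups by their titles, and the submitters' design text speaks of 4 separate experiments. Nothing further in the labels says whether the libraries came from separate cultures, so the p-values measure the spread between these libraries, which may be partly technical. The limma p of copia is an exception, described with its result. Per the labels' protocols, RNA was isolated with a column kit for small samples and libraries were made with a directional kit. Whether the later counting used strand is not given in the sources used here.

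The deposited tables held values per transcript and per transposable element for each of the 8 libraries. The submitters' processing notes name TopHat2, Cufflinks and DESeq2, without versions or roles, and the genome build dm3. The values were taken as FPKM (fragments normalized to transcript length and library size) made by the authors, because they were not whole numbers, their column totals ruled out CPM and TPM, and Cufflinks writes this unit. The gene table had 21081 transcripts, which were summed to 14012 genes by their deposited identifiers, and 3556 genes had more than 1 transcript. Of the identifiers, 13522 were matched to a symbol in the Release 6 annotation table, 5 had a symbol in the deposited table only and 485 had none. Release 6 was used for names, for the order of neighbouring genes and for gene lengths in the check of depth, and no coordinates are given because the authors' build was another. The transposon table had 179 elements, of which 53 were named for other Drosophila species. No column of values was left unused.

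The design fixed before the data were examined assumed counts and named a second test for normalized values, and that second test was used because the tables held FPKM. Genes with an FPKM above 1 in at least 4 libraries were tested on log2(FPKM + 1) with limma's moderated test with a trend, exosome against cell libraries, with no block and with Benjamini-Hochberg adjustment at 0.05. Fold changes are on this log2(FPKM + 1) scale, with a pseudocount of 1, which understates the change of low genes. Transposons were tested in the same way within their own table. Gene lists with at least 5 tested members were compared with all other tested genes by limma's camera with a preset correlation of 0.01, with adjustment over the 16 lists tested, and 3 transposon classes were tested likewise. Single values per library were compared by a two-sided exact permutation test over the 70 splits of 8 libraries, for which the smallest possible p is 0.0286.

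The rule for the genes named in the text was also fixed before the data were examined. It takes Arc1 and Arc2, up to 10 called genes per direction whose groups do not overlap, the 5 genes with the highest mean in each group, up to 2 called members per list and direction, the called transposons and copia. Of the genes this rule takes, 1 is not reported here. No gene was called, so other gene names were chosen after their values were seen, and this is said where they appear. The lists were fixed by symbol. The 13 mitochondrially encoded mRNAs were matched through synonyms as well, and older gene identifiers were used to match symbols in 2 lists; both choices were made after the values were seen. Lists of small nuclear, small nucleolar, transfer, ribosomal and other noncoding RNAs and of microRNA precursors matched 0 genes of the table and were not tested.

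Depth was read from the steps of the values. In the transposon table, values multiplied by an effective length fell on whole multiples of 1 step in 6 libraries, within a tolerance of 0.1 of a fragment for elements with under 20 fragments, which gave fragment counts. In exosome replicate 1 and cell replicate 1 no step was found, and value times length summed to another total than in the other 6 libraries, so these 2 columns were on a different scale. In those 6 libraries, value times length in kilobases summed to much the same total, 1023800 to 1109010. Their transposon values were therefore scaled to the transposon fragments of each library alone, not to library size. In the gene table, genes with 1 transcript and a Release 6 length gave a step in the same 6 libraries. Of their low values, 63.0% (exosome replicate 4) to 89.2% (exosome replicate 2) lay within 0.15 of a whole number. Evenly spread values would give 30%. The step was fitted to these same values, so a share above 30% arises without whole fragments too. Exosome replicate 1 and cell replicate 1, judged to have no step, had 39.8% and 49.1%. The step implies about 97400 fragments in exosome replicate 2, 1850000 and 1910000 in exosome replicates 3 and 4, and 1900000, 2270000 and 6000000 in cell replicates 2, 3 and 4. These are the fragments that the gene values were scaled to, which need not all lie on genes. The depth of both replicates numbered 1 is unknown. Shares of fragments have exact (Clopper-Pearson) 95% intervals, which cover counting error only, because the fragments carry no molecular identifiers.

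A value of 0 in these tables can be a failed estimate. Exosome replicate 1 listed abundant genes at 0, so such genes are described as listed at 0 and each library's value is given. The 28 pairs of libraries were checked for identical columns and 0 were found. The steps were tested on simulated data. For the comparison of genes, simulated data with the spread of the 5868 tested genes and 200 changed genes gave 0% of changes recovered at a log2 fold of 2, 32% at 4 and 77% at 6, with 7 false calls at 6. For the 84 transposons, with 20 changed, 0% were recovered at 2 and 4 and 25% at 6. A list raised by 2 on the log2 scale was called and 0 other lists were. The simulated genes varied independently, while the estimated correlations within the real lists were 0.40 to 0.88. The simulation therefore does not measure how often a list is falsely called in these data.

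Alternatives fixed before the data were examined were the replicate number as a block, each library left out in turn, quantile normalization, no filter, a filter at FPKM 10, pseudocounts of 0.1 and 5, an adjusted p of 0.01, a test for changes beyond 2-fold, joint adjustment of genes and transposons, an estimated correlation, and fry. Others, listed with their results, were added later. Alternatives that need counts were not run. The analysis used R 4.3.3, limma 3.58.1, Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.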

Results

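RNA from S2 exosomes and from S2 cells was compared in 4 libraries each, to find which transcripts exosomes carry. Exosomes are small vesicles that cells release from endosomal compartments. The summed FPKM of the gene table was 850262, 332170, 91304 and 423606 in exosome replicates 1 to 4 and 729519, 1140885, 102736 and 110542 in the cell replicates, a 12.5-fold range. The values are therefore not on an equal scale between libraries. Estimated depth is the number of fragments that the gene values were scaled to. It ran from about 97400 in exosome replicate 2 to 6000000 in cell replicate 4, and is unknown for the replicates numbered 1. In exosome replicate 2, 75.2% of the single-transcript genes above an FPKM of 1 rested on 3 or fewer fragments.

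Exosome libraries did not list a distinguishably different number of genes. Genes above an FPKM of 1 numbered 4382 ± 1252 (SD, n = 4) in exosomes and 5829 ± 1586 (SD, n = 4) in cells, with no difference past the test (two-sided exact permutation p = 0.229). For genes above 0 the difference was -2576 (two-sided exact permutation p = 0.0571), and for genes above 1 it was -1447 with all libraries and -754 with both replicates numbered 1 left out, a choice made after the data were seen. In exosome replicate 2, 3137 genes were above 1 and 3145 above 0, against 3737 and 7042 in cell replicate 4. At such unequal depth an FPKM of 1 is not the same detection level in each library. These counts therefore do not compare the complexity of the RNA. The 100 most abundant genes took 73.6% ± 8.67 (SD, n = 4) of the summed FPKM in exosomes and 63.5% ± 13.1 (SD, n = 4) in cells (two-sided exact permutation p = 0.229). The difference of 10.04 percentage points was 6.19 without exosome replicate 1, 6.65 without cell replicate 1, 6.56 without cell replicate 3, 15.8 without cell replicate 4 and 2.81 with both replicates numbered 1 left out. Across genes, which are not independent replicates, Spearman correlations were 0.788 to 0.889 between cell libraries and 0.779 to 0.904 between exosome replicates 3 and 4 and the cells. They were 0.307 to 0.531 for exosome replicate 1 and 0.307 to 0.619 for exosome replicate 2 against the other libraries.

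Exosome replicate 1 listed 64 of 145 genes (44.1%) at 0 among those with a median FPKM of 200 or more in the other 7 libraries. In each other library at most 1.71% of genes at this level were listed at 0. In exosome replicate 2 the share at 0 was 60.5% at a median of 1 to 10 and 1.53% at 200 or more.

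**Figure D1:**
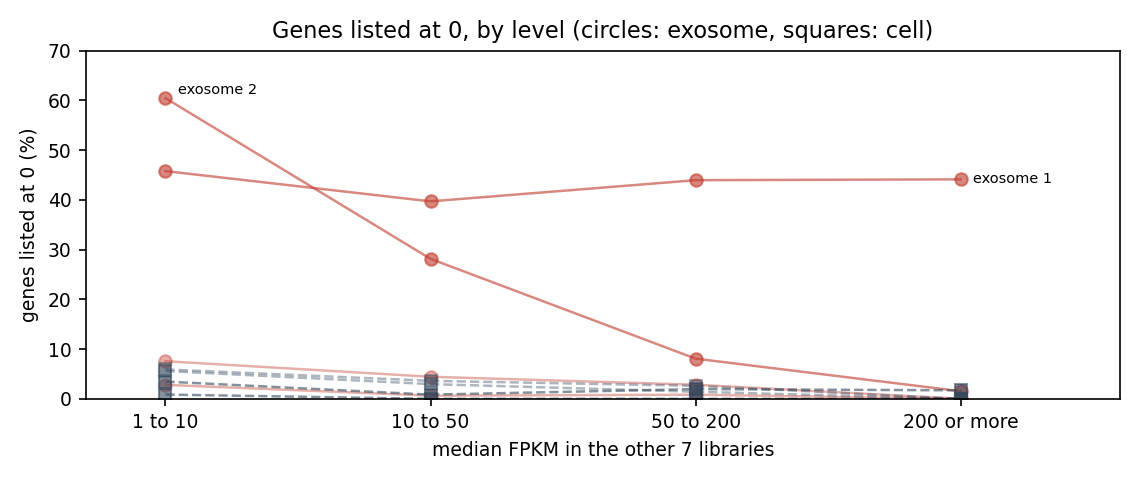
Percent of genes listed at 0 in each library (y axis) by the median FPKM of the gene in the other 7 libraries (x axis), with circles for exosome and squares for cell libraries. Exosome replicate 1 stays between 39.7% and 45.8% at all levels, while exosome replicate 2 falls from 60.5% to 1.53%.

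Arc1 mRNA was far more abundant in exosomes than in cells. Arc1 (CG12505) encodes a protein related to the Gag capsid protein of retrotransposons. Its FPKM was 12766 ± 5098 (SD, n = 4) in exosomes and 547.7 ± 249.6 (SD, n = 4) in cells, a 23.3-fold ratio of means, and the lowest exosome value was 8.86 times the highest cell value (two-sided exact permutation p = 0.0286, the smallest possible with 4 against 4). It was the 7th, 3rd, 1st and 5th most abundant gene of exosome replicates 1 to 4, and ranked 130, 191, 25 and 59 in the cell replicates. As a share of the summed FPKM it held 2.24%, 3.49%, 14.95% and 1.59% in exosomes against 0.104%, 0.0573%, 0.571% and 0.171% in cells (two-sided exact permutation p = 0.0286).

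Arc2 (CG13941), a neighbouring gene of the same kind, had values of 72.6, 699.1, 0 and 0 FPKM in the exosome replicates and 53.8, 214.2, 14.4 and 13.2 in the cell replicates (two-sided exact permutation p = 0.743). Adjusted over these 2 genes, the exact permutation p of Arc1 was 0.0571. Between Arc1 and Arc2 in the Release 6 gene order lies CR10102 (CG10102), annotated as a pseudogene with the synonym Arc3 and chosen here after its values were seen. It was listed at 0, 2833, 8104 and 1439 FPKM in exosomes and 0, 173, 176 and 62.2 in cells. The authors' counting could have split reads between these related neighbours, so their separate levels are uncertain.

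In the fit across all genes Arc1 did not pass. Its log2 fold change was 4.62 (SE 2.13) with an adjusted p of 0.709 from limma, higher in 4 of 4 exosome libraries than in every cell library. Adjusted over the list alone, the retrotransposon Gag-derived genes with 2 tested members, the limma adjusted p of Arc1 was 0.0606. With both libraries numbered 1 left out, the exact permutation p was 0.1, the smallest that 3 against 3 allows, and without any one of the cell libraries it was 0.0571.

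**Figure D2:**
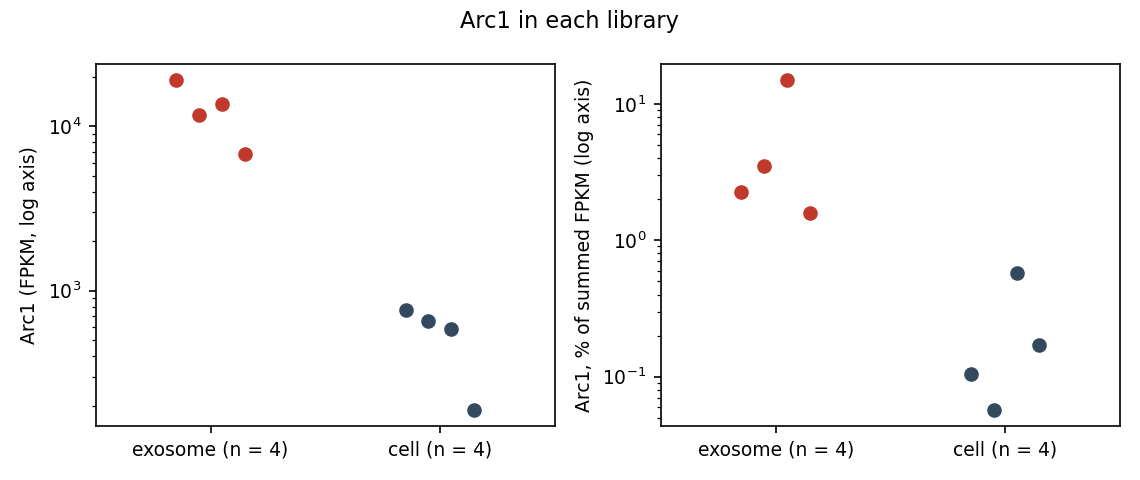
Arc1 in each library, as FPKM (left) and as percent of the summed FPKM (right), both on log axes, with 1 point per library and 4 libraries per group. All exosome points lie above all cell points, at 6749 to 19061 FPKM against 189 to 761 FPKM.

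The most abundant exosome mRNAs other than Arc1 were also abundant in cells. By mean FPKM, in which libraries with a larger sum weigh more, the 5 highest in exosomes were CG34335, MtnA, Arc1, RpL41 and RpS26, and among the 5 highest in cells were MtnA, CG41421, Nplp2 and RpL41. MtnA encodes a metallothionein, a metal-binding protein, and was listed at 0, 29638, 4752 and 26476 FPKM in exosomes and 5667, 67976, 5665 and 2863 in cells. RpL41, a ribosomal protein of the large subunit, had 29178, 10280, 749.2 and 8653 FPKM in exosomes and 5384, 35070, 1604 and 1513 in cells. RpS26, of the small subunit, had 30885, 3760, 213.8 and 3524 in exosomes and 8925, 14724, 378.5 and 456.3 in cells. CG34335 was listed at 0, 23629, 3690 and 104560 FPKM in exosomes and at 3361, 13888, 4170 and 3275 in cells. CG41421 had 52093 FPKM in cell replicate 4, 0 to 2444 in the other cell replicates and 0 to 4174 in exosomes. Nplp2 ranged from 572.6 to 16010 in exosomes and from 1198 to 29598 in cells. None of these 7 genes, Arc1 included, passed the limma test, with adjusted p from 0.709 to 0.970.

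Across the 5868 genes tested, limma called 0 genes higher and 0 lower in exosomes, and at an unadjusted p under 0.05 there were 5 higher and 271 lower. The latter count was 58 without cell replicate 2, 88 without cell replicate 1, 95 without exosome replicate 1 and 1213 without cell replicate 4. The median log2 difference of all tested genes was -1.01 (-0.54 without cell replicate 1, -0.61 without cell replicate 2 and -1.58 without cell replicate 4), so the 2 groups were not centred on each other, and with quantile normalization, where the median was 0.11, 0 were called and the unadjusted counts were 206 higher and 156 lower. In 2 genes all exosome libraries lay above all cell libraries and in 44 all lay below, where chance gives 1.43% or 83.8 genes each way. By rank within the library these numbers were 147 and 121.

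The 2 genes with all exosome values higher were Arc1 and CG5381, named after the values were seen. CG5381 had 9.32, 19.9, 12.5 and 37.0 FPKM in exosomes and 0, 3.74, 7.56 and 0 in cells, with a limma adjusted p of 0.709. Among the 44, also named after the values were seen, were PH4alphaEFB, a prolyl hydroxylase subunit that modifies collagen, and P58IPK, a co-chaperone of the endoplasmic reticulum. PH4alphaEFB had 0, 0, 2.75 and 4.93 FPKM in exosomes against 404.7, 167.4, 28.3 and 12.4 in cells, and P58IPK had 0, 9.91, 6.09 and 5.003 against 128.4, 231.6, 48.3 and 13.9. Dph3 was listed at 0 in all 4 exosome libraries and at 38.9, 186.2, 6.43 and 7.23 FPKM in cells. Gp150, a leucine-rich repeat membrane protein, had 2.89, 4.98, 2.42 and 2.23 FPKM in exosomes and 231.4, 66.2, 29.7 and 5.09 in cells. None of these passed limma's test (adjusted p = 0.709).

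Mitochondrially encoded mRNAs, which specify subunits of the respiratory chain, were lower in exosomes relative to the other genes. All 10 tested members lay below the median of all genes, with a median log2 difference of -3.19 (limma camera, adjusted p = 6.7e-08). The adjusted p was 0.978 with an estimated correlation. With each library left out, the median log2 difference ran from -5.03 without exosome replicate 2 to -2.41 without cell replicate 2. No member was called over all genes by limma, and adjusted over the list alone 5 were (COX3, COX1, ND1, COX2 and CYTB, with adjusted p from 0.0101 to 0.0324). COX3 and COX1 were chosen after their values were seen. COX3 was listed at 0, 466.6, 2.57 and 3.73 FPKM in exosomes and at 610.9, 2112, 322.1 and 119.7 in cells. COX1 was listed at 0, 165.3, 3.82 and 3.33 in exosomes and at 112.4, 684.9, 109.1 and 53.7 in cells. The members together held 0%, 0.470%, 0.0112% and 0.00364% of the summed FPKM in the exosome replicates and 0.137%, 0.735%, 0.468% and 0.424% in the cells (two-sided exact permutation p = 0.114). All 10 were listed at 0 in exosome replicate 1.

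Markers of plasmatocytes, the macrophage-like blood cells that S2 cells resemble, were also lower relative to the other genes (limma camera, adjusted p = 0.0326, or adjusted p = 0.978 with an estimated correlation). Of 16 tested members 14 lay below the median of all genes, with a median log2 difference of -1.79 (-0.94 without cell replicate 1 and -2.67 without cell replicate 4), and 0 were called over all genes or adjusted over the list alone by limma. SPARC and LanB1 were chosen after their values were seen. Their log2 differences of -3.96 and -2.70, neither of which was called, lay below the median of the list. SPARC, a collagen-binding matrix protein, had 0, 41.6, 1.57 and 20.46 FPKM in exosomes and 3003, 365.6, 7.73 and 13.4 in cells. LanB1, a laminin chain, had 11.03, 5.21, 4.12 and 2.19 in exosomes and 489.3, 54.9, 11.4 and 5.37 in cells. The call was lost without exosome replicate 3 (limma adjusted p = 0.0529), exosome replicate 4 (0.727) or cell replicate 1 (0.269). With the library as the unit, the mean log2 value of the list less that of all tested genes differed by -0.855 (two-sided exact permutation p = 0.143).

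Translation initiation and elongation factors were higher relative to the other genes, with 15 of 23 above the median of all genes (limma camera, adjusted p = 0.00536, or adjusted p = 0.978 with an estimated correlation). Their median log2 difference was 0.10 and their mean -0.42, and 10 of 23 lay below 0. The median ran from -0.71 without cell replicate 4 to 0.66 without cell replicate 2, so its sign was not stable, and 8 were listed at 0 in exosome replicate 1. The 2 members given here, pAbp and eIF1, were chosen after their values were seen and lie above the median of the list, with log2 differences of 1.36 and 1.04. The poly(A)-binding protein gene pAbp had 1553, 421.3, 84.6 and 379.9 FPKM in exosomes and 619.3, 477.5, 56.1 and 28.0 in cells. The initiation factor gene eIF1 had 1053, 232.9, 34.5 and 242.5 in exosomes and 358.4, 398.1, 41.1 and 18.7 in cells. None of the 23 was called by limma over all genes or adjusted over the list alone. With the library as the unit, their mean log2 value less that of all tested genes differed by 0.561 (two-sided exact permutation p = 0.2). The call was lost with the filter at FPKM 10 (limma camera, adjusted p = 0.342) and with quantile normalization (0.715).

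Cytosolic ribosomal protein mRNAs gave no stable direction. Of 80 tested members 47 lay above the median of all genes, and the list was higher relative to the other genes (limma camera, adjusted p = 0.0158, or adjusted p = 0.978 with an estimated correlation). Its median log2 difference was 0.20 and its mean -0.96, and 34 members were listed at 0 in exosome replicate 1. With the library as the unit, its mean log2 value less that of all tested genes differed by 0.0228 (two-sided exact permutation p = 0.971). With quantile normalization it was called lower (limma camera, adjusted p = 0.00369). The call was lost with the filter at FPKM 10, where the direction was lower (0.903), and without exosome replicate 2 (0.976), exosome replicate 4 (0.307), cell replicate 1 (0.0843) or cell replicate 3 (0.213).

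Replication-dependent histone genes were higher relative to the other genes, with 44 of 46 above the median of all genes (limma camera, adjusted p = 1.09e-06, or adjusted p = 0.978 with an estimated correlation). Their median log2 difference was 0.02 and their mean -0.14. Their mean log2 value less that of all tested genes was -2.24, -0.93, 0.44 and -2.27 in the exosome replicates. In the cell replicates it was -4.82, -3.55, 0.06 and -0.09 (two-sided exact permutation p = 0.514). The pseudocount understates the change of low genes, so a difference near 0 can place such genes above the median of all genes. All 46 were listed at 0 in exosome replicate 1, and as near-identical copies they share reads, so their number is not a number of independent genes. The call was lost without exosome replicate 3 (limma adjusted p = 0.898), and without cell replicate 1 the direction turned (0.335). It was lost as well with both replicates numbered 1 left out (0.185), and the list was not tested with the filter at FPKM 10, where fewer than 5 members were left. For both this list and the ribosomal proteins 0 members were called by limma over all genes or adjusted over the list alone.

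**Figure D3:**
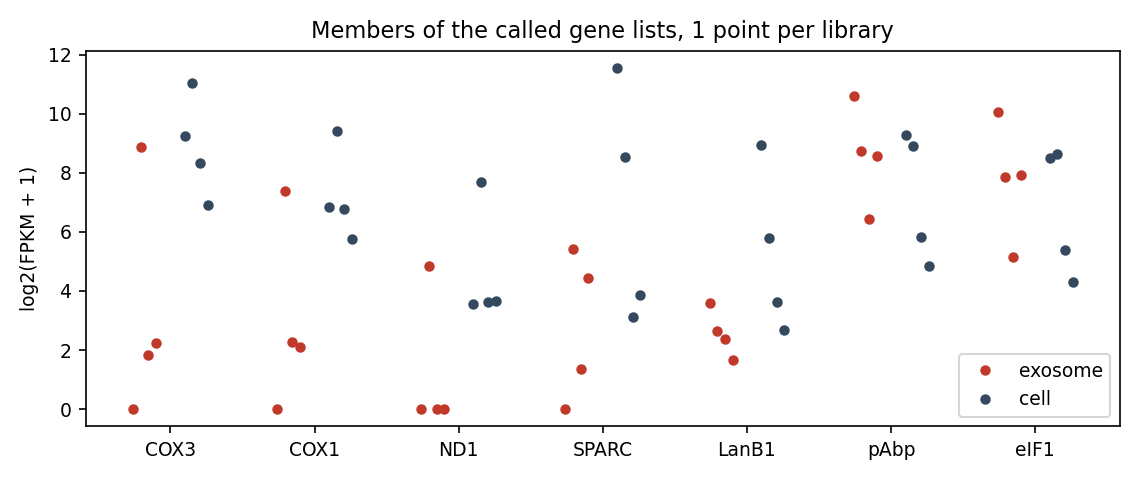
Levels of members of the called lists as log2(FPKM + 1) on the y axis, with 1 point per library, exosomes in red and cells in dark blue. COX3 and COX1 lie lower in exosome replicates 1, 3 and 4 than in all cells and within the range of the cells in exosome replicate 2, and the translation factors pAbp and eIF1 overlap between the groups.

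The other 11 lists did not pass limma's camera in the fit fixed beforehand. Adjusted p was 0.0964 for mitochondrial ribosomal proteins, 0.1497 for the nuclear-encoded respiratory chain, 0.193 for endoplasmic reticulum import and folding, 0.233 for heat shock proteins, and 0.659 for both the cytoskeleton and the proteasome. It was 0.809 for endosomal sorting and vesicle proteins, glycolysis and the cell cycle, 0.864 for histone variants and 0.943 for small RNA pathways. Each list had 0 called members by limma. Of the heat shock and chaperone genes 17 of 19 lay below the median of all genes, and of the genes of endoplasmic reticulum import and folding 25 of 33. Both lists were lower in limma's camera with quantile normalization (adjusted p = 0.000101 and 3.15e-07) and with the filter at FPKM 10 (0.00271 and 0.00463), and neither was with an estimated correlation (adjusted p = 0.978). The heat shock list was also lower without exosome replicate 2 (limma camera, adjusted p = 0.000727) or cell replicate 1 (4.61e-06), and the endoplasmic reticulum list without exosome replicate 2 (0.0405). The direction of the heat shock list turned without exosome replicate 1 (limma camera, adjusted p = 0.856) or cell replicate 2 (0.994). Mitochondrial ribosomal proteins were called higher without exosome replicate 2 (limma camera, adjusted p = 0.0102), exosome replicate 3 (0.0196), cell replicate 1 (0.00687) or cell replicate 2 (0.00781). The nuclear-encoded respiratory chain was called higher without exosome replicate 1 (0.0014) or cell replicate 2 (0.0468). With all libraries and an estimated correlation, the adjusted p was 0.978 for both of these lists, and also for the cytoskeleton and the proteasome. With both replicates numbered 1 left out, a choice made after the data were seen, the respiratory chain (0.000102) and the cytoskeleton (0.0332) were called higher and heat shock proteins lower (0.000469). With quantile normalization the proteasome was called lower (0.0378), but not with an estimated correlation as well (0.526). Markers of crystal cells and lamellocytes, germ line, neuron, muscle, and fat body and midgut had 3, 2, 1, 1 and 0 tested members and formed no tested list.

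Among transposons, copia stood out in exosomes. It is a retrotransposon with long terminal repeats. Its share of transposon fragments was 38.7% (95% interval 31.8 to 46.0), 70.8% (67.2 to 74.3) and 89.9% (88.8 to 91.0) in exosome replicates 2, 3 and 4. It was 22.2% (19.9 to 24.8), 11.8% (5.56 to 21.3) and 4.35% (2.27 to 7.47) in cell replicates 2, 3 and 4. These shares rest on 74 of 191, 466 of 658 and 2479 of 2756 fragments in exosomes and on 255 of 1147, 9 of 76 and 12 of 276 in cells, and the exosome intervals lie above the cell intervals. Per 1000000 fragments that the gene values were scaled to, copia had 759.8, 251.9 and 1298 fragments in these exosome libraries. It had 134.2, 3.96 and 2.0 in these cell libraries.

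Over all 8 libraries, copia held 54.4% ± 32.2 (SD, n = 4) of the length-weighted transposon value in exosomes and 9.62% ± 9.74 (SD, n = 4) in cells (two-sided exact permutation p = 0.0571). The replicates numbered 1 held 17.97% in exosomes and 2.69e-09% in cells, from columns on another scale. Without exosome replicate 1 the two-sided exact permutation p was 0.0286, without cell replicate 1, 3 or 4 it was 0.114, and without any of the others 0.0571. With both replicates numbered 1 left out it was 0.1, the smallest possible exact p of 3 against 3.

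Of 84 transposons tested, limma called 1 higher, which was copia, and 0 lower, with 1 higher and 1 lower at an unadjusted p under 0.05. The latter count was 17 without cell replicate 3, 4 without exosome replicate 2 and 0 to 3 without each other library. The log2 fold change of copia was 5.44 (moderated SE 1.07, limma adjusted p = 4.89e-05), while its own SE without moderation was 3.71. The moderation gave infinite weight to the trend over the elements. This limma p therefore does not measure the spread of copia itself between libraries. The FPKM of copia was 17846, 79482, 141623 and 179066 in exosomes and 6.8e-05, 44516, 25600 and 8993 in cells. Outside the replicates numbered 1 these values are relative to the transposon fragments of a library, so they cannot be set against the FPKM of genes. The fold change is thus one of share among transposons, in which a higher share of copia lowers that of the other elements. Without cell replicate 1 the log2 fold change was 1.83 (limma adjusted p = 0.734), and with quantile normalization (0.949), no filter (0.789) or without exosome replicates 1 and 2 and cell replicate 1, a choice made after the data were seen (0.259), the call was lost as well. Over all alternatives its limma adjusted p ran from 7.48e-09 to 0.955. Of 3 classes, limma's camera called 0, with adjusted p of 0.391 for elements with long terminal repeats, 0.512 for other retrotransposons and 0.512 for DNA transposons, and with 0 classes at an unadjusted p under 0.05.

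**Figure D4:**
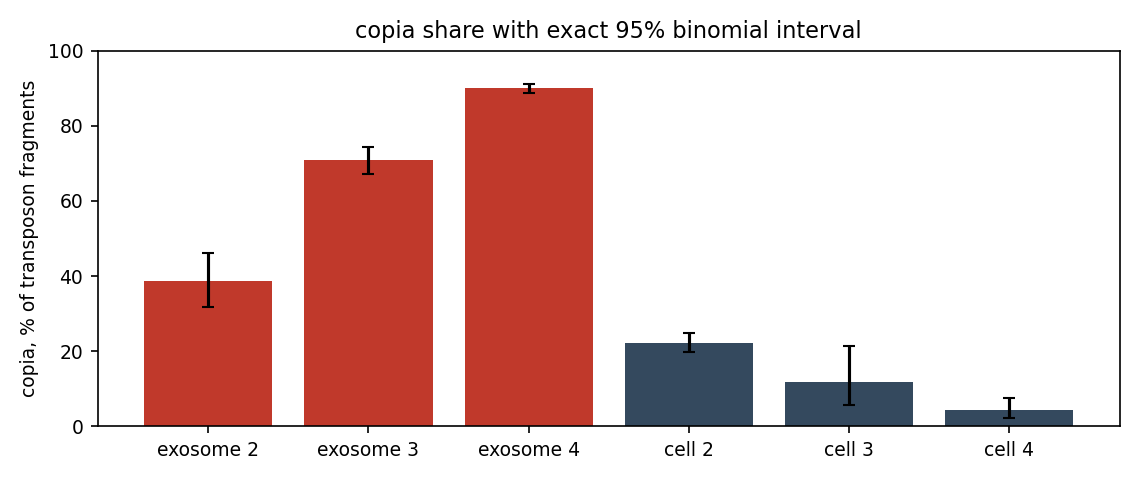
Share of transposon fragments from copia (y axis, percent, from 0) in the 6 libraries whose values fell on whole fragments, with exact 95% binomial intervals. The exosome bars run from 38.7% to 89.9% and the cell bars from 4.35% to 22.2%.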

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

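The tests of explanations in this part were all chosen after the results they measure had been seen, while the rule that picks out a library far from the other 3 of its group was set before the data were examined. That rule picked 3 of 26 groups of 4 libraries, and chance picks about 1 in 20.

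Arc2 stood at 699.1 FPKM in exosome replicate 2, far from the 72.6, 0 and 0 FPKM of the other exosome libraries. The gene values of that library were scaled to about 97400 fragments.

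Arc1 held 14.95% of the summed FPKM in exosome replicate 3, against 1.59% to 3.49% in the other exosome libraries, and was higher in every exosome library than in every cell library. The unequal scale of the libraries is argued against, because the lowest exosome share of the summed FPKM was still 2.79 times the highest cell share. Reads shared between Arc1 and its neighbour CR10102 remain a candidate explanation for the level of CR10102 or for part of that of Arc1. Where both were above 0, the ratio of CR10102 to Arc1 was 0.244, 0.594 and 0.213 in exosomes and 0.264, 0.300 and 0.329 in cells, a mean log2 difference of 0.0824 within a spread of 0.578 (SD). A like ratio in both groups would also be seen if both genes were higher in exosomes, so it does not decide between shared reads and a joint rise. The sorting of Arc1 mRNA into exosomes is the biological explanation that the design names. It stays open, because no test here addressed it and these data do not separate the 2 genes.

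Mitochondrially encoded mRNAs held 0.470% of the summed FPKM in exosome replicate 2, within the range of the cells, and at most 0.0112% in the other exosome libraries. As an account of the lower list, the unequal scale of the libraries is not settled by camera. With the preset correlation the list was called after quantile normalization and median-ratio scaling (limma camera, higher adjusted p = 0.000364). On the deposited scale, however, camera called it in 24 of 35 splits of the libraries, the real one included. With an estimated correlation the adjusted p after quantile normalization was 0.372. The median log2 difference was -2.60 after quantile normalization and -3.19 after median-ratio scaling. The list's mean log2 value less that of all tested genes gave a two-sided exact permutation p of 0.229. Low depth was examined in exosome replicates 3 and 4 and cell replicates 2 and 3, whose values were scaled to 1850000 to 2270000 fragments. The median log2 difference between them was -5.33, negative in 10 of 10 members. Single-transcript genes above an FPKM of 1 had medians of 8 and 15 fragments in these exosome libraries and 37 and 10 in these cell libraries. Coverage of genes was thus not matched, but exosome replicate 4, with a median of 15 fragments, was covered no less than cell replicate 3, with 10. A difference of -5.33 shared by 10 of 10 members argues against low depth as its source in these libraries. Exosome replicate 2 was left out and the depth of exosome replicate 1 is unknown, so low depth is not excluded for them. A lower content of mitochondrial mRNAs in exosomes stays open as a hypothesis. Exosome replicate 2, the library with the fewest fragments of the 6 whose depth could be read, goes against it when set against all cells. Its share was below the 0.735% of cell replicate 2. By number, which did not clearly pair the libraries, each exosome share was below its cell share, with exosome replicate 1 at 0%.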

How the results depend on the processing

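Alternatives chosen after the data were seen were library-total and median-ratio scaling, library quality weights, experiment 1 or 3 libraries (exosome 1 and 2, cell 1) left out, values at 0 treated as missing, transcripts tested separately, quantile normalization with an estimated correlation or with the replicate block, and mitochondrial genes matched without synonyms. Alternatives that need counts, namely count models, their size factors, library totals of counts and quality weights on counts, were not run.

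limma called 0 genes in each direction under all settings run but these. With experiment 1 left out, median-ratio scaling and the replicate block, 2 were higher (Arc1 and CR10102, adjusted p = 0.0453 each, range over the alternatives for Arc1 0.0453 to 0.9998). With median-ratio scaling and library quality weights, 1 was higher and 9 were lower, COX3 (adjusted p = 0.0066), COX1 (0.035), PH4alphaEFB (0.027) and P58IPK (0.035) among them. The cause was not tested. Transposons higher in exosomes fell from 1 to 0 with quantile normalization (also with the block), no filter and 3 libraries left out, and were 0 to 1 with each library left out. The Arc1 difference was 10191 FPKM with experiment 1 left out (exact permutation p = 0.1), where 3 against 3 allows no less, and 10120 to 14224 with each library left out (exact permutation p from 0.0286 to 0.0571). The difference in copia share was 33.0 to 57.0 percentage points with each library left out.

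Lists called numbered 0 with an estimated correlation, 0 with fry, which compares no list with other genes, and 0 with quantile normalization and an estimated correlation. They numbered 10 with experiment 1 left out and median-ratio scaling, 10 with 3 libraries left out, and 3 to 7 with each library left out. Cytosolic ribosomal proteins turned lower with quantile normalization (limma adjusted p = 0.00369), the stricter filter (0.903) and quantile normalization with an estimated correlation (0.372), and histones turned lower without cell replicate 1 (0.335), with 8.77e-17 to 0.898 for the other libraries left out in turn. The cause was not tested. Over the alternatives the adjusted p of each called list reached 0.978, from 8.84e-48 for mitochondrially encoded mRNAs, 8.77e-17 for histones, 0.000105 for plasmatocyte markers, 0.000138 for ribosomal proteins and 0.000541 for translation factors.

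The replicate numbers did not clearly pair the libraries. Correlations of same-numbered deviations across genes were 0.23, 0.19, 0.45 and -0.07, and 5 of 8 libraries correlated best with their own number. After median-ratio scaling they were 0.28, 0.17, 0.44 and 0.08, again with 5 of 8. Both replicates numbered 1 also lacked whole-fragment steps. A pairing is thus neither shown nor excluded. Within each number, Arc1 FPKM in exosomes was 25.0, 17.7, 23.3 and 35.7 times that in cells. With the replicate block limma called 0 genes, 1 transposon and 6 lists, without ribosomal proteins (adjusted p = 0.207) and with heat shock proteins (0.0415) and endoplasmic reticulum import and folding (0.0313), both lower. These block calls used the preset correlation. With an estimated correlation and no block both lists had a camera adjusted p of 0.978. Of the 6 libraries whose depth could be read, depth limits exosome replicate 2 most, where single-transcript genes above an FPKM of 1 had a median of 2 fragments.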

Other observations

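The tests in this part, of other splits of the libraries and of the genes listed at 0, were all chosen after the results they measure had been seen.

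Some genes of the secretory pathway and chaperones had lower mean log2 values in exosomes, with ranges that overlapped those of the cells. The endoplasmic reticulum chaperones Gp93, Calr and Hsc70-3, chosen after their values were seen, had log2 differences of -3.34 (SE 1.75), -3.32 (SE 1.85) and -3.07 (SE 1.79) with a limma adjusted p of 0.709 each, and were listed at 0 in exosome replicate 1. Without that library the log2 differences were -1.77, -1.41 and -1.32. The median over all tested genes was -1.01 with all libraries and -0.95 without that library, so much of these differences was shared by genes in general. In exosome replicates 2 to 4 Calr had 309.2, 130.5 and 202.0 FPKM, against 1690, 1901, 268.8 and 94.7 in the cells. The inducible chaperone Hsp68, chosen after its values were seen as was DnaJ-1, was listed at 0, 103.6, 7.83 and 19.9 FPKM in exosomes and at 25.6, 789.2, 55.1 and 49.9 in cells, and its co-chaperone DnaJ-1 at 9.19, 43.8, 12.8 and 16.8 in exosomes and 46.2, 344.2, 85.5 and 23.2 in cells.

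Counts of calls were compared with those of other splits, over the 35 splits of the 8 libraries into 4 and 4. As many genes were called as in the real split (0) in 35 splits, the real one included, with a highest other count of 214. That split set exosome replicates 1 and 3 with cell replicates 3 and 4 against the rest, and the next, with 147, set exosome replicates 1 and 4 with cell replicates 1 and 2 against the rest. Such counts point to a structure of the samples other than the groups on the deposited scale. In the split with 147 this structure follows the scale of the libraries. Its first 4 libraries had a summed FPKM of 423606 to 1140885, and the rest at most 332170. With quantile normalization the highest other count was 3. With a real count of 0 every split gives as many, so this says nothing about chance. As many transposons (1) were called in 9 splits, with a highest other count of 1. As many lists (5) were called in 20 splits, with a highest other count of 10. The mitochondrially encoded mRNAs were called in 24 splits, and their median log2 difference of 3.19 in absolute size was reached in 4, the real one included, with 4.67 as the highest other. The others that reached it (4.36, 4.67 and 3.96) kept exosome replicates 1, 3 and 4 together. They exchanged exosome replicate 2 for cell replicate 1, 3 or 4, so they hold most of the real contrast. As many classes (0) were called in 35 splits, with a highest other count of 2, again with no bearing on chance. Chance cannot be excluded for the counts of transposons and lists.

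Exosome replicate 1 listed 64 abundant genes at 0. Low depth of that library is argued against, because 44.14% of genes with a median of 200 FPKM or more in the other libraries were at 0, a share that did not fall with level. Absence of these mRNAs from exosomes is argued against as well, because 96.88% of the genes at 0 (62 of 64) were above 10 FPKM in each of the other 3 exosome libraries. Failed estimates of the quantification may be the source of these zeros, which no test here addressed, and no other biological explanation was tested.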
